A study of Homo sapiens with 13 samples.

How the data were processed

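Gene-level RNA levels were measured in 13 libraries of human muscle biopsies, 7 in a table for the 24 h comparison and 6 in a table for the training comparison. Per the labels' protocols, the 24 h libraries were made with the Watchmaker mRNA kit and the training libraries with the SMART-Seq mRNA LP kit, and both were sequenced as paired reads of 51 nt on an Illumina NextSeq instrument. Values in both tables are TPM as deposited by the authors, scaled so that each library has the same sum. Per the submitters' processing notes, the tools named are Trim Galore 0.6.10 and Salmon 1.10.3 and the genome build is GRCh38, while the annotation release and the use of strand are not given in the sources used here. Salmon estimates transcript abundance from reads, so genes that share reads with a near-identical copy, pseudogenes and overlapping antisense genes are uncertain. TPM keep no depth, so no counting interval or detection floor can be given, and TPM are shares, so a large rise in abundant transcripts lowers all others.

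Both tables list the same 62703 genes, of which 41737 carry a symbol other than their identifier. For coordinates and gene types on GRCh38, 58279 identifiers matched GENCODE 29. XIST, TSIX and Y-linked genes (513) were removed from every table and test. Columns were mapped to samples by name, and 0 sample columns were left unmapped. Groups came from the labels. Volunteer numbers in the training labels were recoded as pairs 1 to 3. No pair of libraries held identical values, and correlations between libraries were 0.968 to 0.978 in the 24 h table and 0.942 to 0.976 in the training table. The labels do not say whether the libraries at rest and at 24 h came from separate volunteers, so p-values there measure the spread between these libraries.

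The test, the samples, the covariates, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where a choice is said to have come later. Genes with at least 1 TPM in at least 3 libraries of a table were tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with an intensity trend in the empirical Bayes step, 2-sided, and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(TPM + 1) scale, which understates changes of low genes. The 24 h comparison was fitted without a block and the training comparison with the volunteer as a block. The pairing in training comes from the design text and the labels, and same-numbered libraries deviated together (correlations 0.28 to 0.35, against -0.20 to -0.11 for other numbers, with the own number best in 3 of 3). The difference between the responses was fitted over all 13 libraries, each table with its own intercept and effect. Of the 43 gene lists, those with at least 5 tested members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, and 2 list members had no match. Shares were compared with 2-sided exact permutation tests, 4 in the family.

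The named genes were, per comparison, the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap (24 h) or whose 3 pairs agreed in direction (training), with a mean of at least 5 TPM in the higher group. Empty places were filled by the smallest unadjusted p. Identifiers without a symbol, pseudogenes and genes with common null alleles or haplotype effects were not named. Added to these were the 3 members with the smallest p in the direction of each called list, and 22 genes fixed in advance. A subset is printed. Of the 22, TNC stayed below the filter at 24 h (at most 0.499 TPM) and PAX7 in training (at most 1.40 TPM).

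Alternatives were pseudocounts of 0.1 and 5, no filter, a minimum mean of 5 TPM, median-of-ratios scaling, removal of mitochondrially encoded genes, quantile normalisation, array weights, no intensity trend, a 2-fold minimum, the other choice of block (which at 24 h also leaves out rest replicate 4, as no library at 24 h has its number), and leaving out each library or pair. Removal of a trend on transcript length and GC content was added after the data were seen. Tables were handled with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9. The fits were tested on simulated data with 200 changed genes. In the 24 h design, on 11863 genes, 4.48% of changes of 0.5 on the log2 scale were called, 86.6% of 1 and 100% of 2, with 8 of 11635 unchanged genes called. In the training design, on 12824 genes, the shares were 10.4%, 82.1% and 100%, with 5 of 12596 unchanged genes called. For the difference, on 10662 genes, 99% of changes of 2 were called, with 9 of 10462 unchanged genes. A simulated shift of 0.5 in 1 list passed camera with the preset correlation in both designs. With an estimated correlation it passed in the 24 h design (adjusted p = 0.00227) and not in training (adjusted p = 0.416). The simulated noise was independent between genes, and the 200 changed genes had a mean of at least 5 TPM. The simulation thus tested neither low genes nor camera's preset correlation on genes that vary together.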

Results

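RNA from human thigh muscle biopsies was sequenced in 2 settings. In the first, vastus lateralis (an outer thigh muscle) was sampled at rest (n = 4 libraries) or 24 h after eccentric exercise (n = 3), a downhill treadmill run of 40 min at a grade of -15% and 60% of maximal oxygen uptake, in volunteers with no earlier exercise programme. Eccentric exercise loads a muscle while it lengthens. In the second, quadriceps femoris (the muscle group at the front of the thigh) was sampled before (n = 3) and after (n = 3) 6 weeks of resistance training in the same volunteers, so these libraries form 3 pairs. Levels were deposited as TPM, a length-corrected share of all transcripts, which keep no record of sequencing depth, so the depth behind each value is unknown. In the 24 h table, 11346 to 11779 genes reached 1 TPM in a library, and 12275 to 13491 did in the training table. Mitochondrially encoded transcripts made up 34.4% ± 3.80 (SD, n = 4) of TPM at rest and 39.0% ± 1.92 (n = 3) at 24 h, which did not pass a 2-sided exact permutation test (p = 0.114, adjusted p = 0.229 over 4 tests). They made up 10.7% ± 1.83 before and 9.72% ± 0.591 after training (n = 3 each, exact sign-flip permutation p = 0.5, the smallest possible being 0.25). Each table was analysed on its own because the muscle named, the intervention and the library kit differ between them, and the muscle sampled and the volunteers may.

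The first comparison asked what differed in muscle 24 h after the eccentric run. Genes of fast-twitch fibres, which contract quickly and tire early, were lower: all 12 tested members had lower means, with a median log2 change of -0.56. Fast troponin C, TNNC2 (chromosome 20, 45823214 to 45833745), had 10547 ± 568 TPM (SD, n = 4) at rest and 6739 ± 1044 (n = 3) at 24 h. The fast troponin I gene TNNI2 had 5315 ± 282 and 3754 ± 378 TPM, the fast myosin light chain gene MYL11 8251 ± 1017 and 5204 ± 940, and the fast myosin heavy chain gene MYH2 4212 ± 312 and 2888 ± 562. Of the slow-twitch fibre genes, 11 of 12 had higher means (median 0.23). The slow myosin heavy chain gene MYH7 (chromosome 14, 23412738 to 23435718) had 3904 ± 763 TPM at rest and 5147 ± 971 at 24 h, and MYH7B 49.9 ± 7.75 and 73.7 ± 14.5. Both lists passed limma's camera test, which compares a list with all other genes (adjusted p = 7.14e-09 for fast and 0.00029 for slow fibre genes). With an estimated correlation between genes, neither passed: adjusted p = 0.538 for fast and adjusted p = 0.560 for slow fibre genes. No member of either list passed over all genes, and 8 fast fibre genes fell when adjusted over the list alone. Without the 24 h library of replicate 1, the slow fibre list no longer passed (median 0.04, adjusted p = 0.0686), and its median was 0.36 without that of replicate 2.

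The share of MYH7 in the summed TPM of MYH7, MYH2 and MYH1, a measure chosen after the data were seen, was 44.0% ± 4.99 (SD, n = 4) at rest and 61.1% ± 9.21 (n = 3) at 24 h. All 3 libraries at 24 h lay above all 4 at rest (2-sided exact permutation p = 0.0286, the smallest that the 35 arrangements allow), and the adjusted p over 4 tests was 0.114. The lowest at 24 h, replicate 2, had 50.9% and the highest at rest, replicate 1, had 49.3%. Before and after training the share was 39.9% ± 12.5 and 44.6% ± 18.8 (n = 3 each, exact sign-flip permutation p = 0.5, the smallest possible being 0.25).

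**Figure D1:**
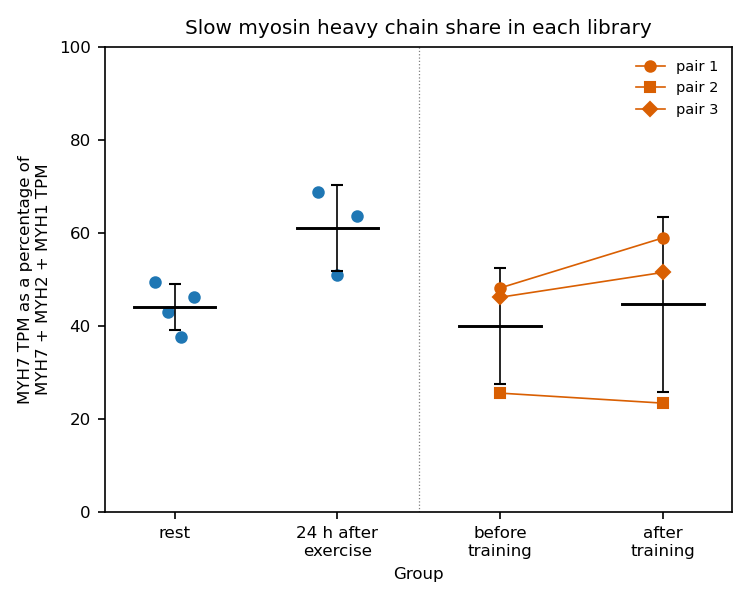
MYH7 TPM as a percentage of the summed TPM of MYH7, MYH2 and MYH1 (vertical axis) in each library of the 4 groups (horizontal axis); points are libraries, lines join the 3 training pairs, and bars give the group mean ± SD. The 24 h libraries average 61.1% against 44.0% at rest.

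Respiratory chain, mitochondrial genome, tricarboxylic acid cycle, heat shock and sarcomere stress lists were also higher at 24 h. Of 49 nuclear genes for respiratory chain subunits, 44 had higher means (median 0.10), for example SDHC with 100.4 ± 3.60 TPM at rest and 118 ± 7.86 at 24 h. Of 13 protein-coding transcripts of the mitochondrial genome, 12 had higher means (median 0.20), and of 17 tricarboxylic acid cycle genes, 13 did (median 0.06). Camera gave adjusted p = 7.14e-09, 4.49e-07 and 0.00354 for these lists, and adjusted p = 0.538 with an estimated correlation for each. Other energy lists did not pass: glycolysis and glycogen genes had lower means in 16 of 21 (median -0.13, camera adjusted p = 0.589) and fatty acid genes in 14 of 19 (median -0.0864, adjusted p = 0.973, with the opposite sign in the test relative to other genes). After quantile normalisation the mitochondrial genome list missed the threshold (median 0.14, adjusted p = 0.0541). The respiratory chain median was 0.06 without 24 h replicate 1, 0.16 without 24 h replicate 3 and 0.19 after median-of-ratios scaling, and that of the tricarboxylic acid cycle list was 0.02 without rest replicate 2, 0.10 without 24 h replicate 3 and 0.14 after that scaling, with both calls kept. Heat shock chaperones, which help proteins fold under stress, had higher means in 14 of 16 members (median 0.22), with HSP90AA1 at 137 ± 11.8 and 224 ± 79.3 TPM and HSPB1 at 1052 ± 393 and 1549 ± 376. Genes of sarcomere and cytoskeleton stress had higher means in 11 of 16 and lower means in 5 (median 0.25). Among the higher ones the Z-disc protein gene CSRP3 had 690 ± 208 TPM at rest and 1501 ± 710 at 24 h, MUSTN1 538 ± 153 and 1256 ± 678, and the actin cross-linker gene FLNC 564 ± 131 and 883 ± 280. These lists had adjusted p = 4.75e-05 and 0.000112 with camera, and adjusted p = 0.538 and 0.560 with an estimated correlation. The size of both medians depended on single libraries, though the camera calls did not: the sarcomere median was 0.08 without 24 h replicate 1, 0.16 without 24 h replicate 2, 0.55 without 24 h replicate 3, 0.50 without rest replicate 1, 0.13 without rest replicate 4 and 0.40 after quantile normalisation. The heat shock median was 0.06 without rest replicate 2 and 0.13 without 24 h replicate 1. None of the genes named in this paragraph passed over all genes.

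Lower at 24 h were genes linked to muscle atrophy and the FOXO factors, in which all 14 tested members had lower means (median -0.31). The ubiquitin ligase gene FBXO32 had 149 ± 61.6 TPM at rest and 71.1 ± 45.0 at 24 h, FOXO3 7.35 ± 2.55 and 3.76 ± 0.568, and MSTN, the gene of the growth inhibitor myostatin, 3.25 ± 0.512 and 1.81 ± 0.652. The list had an adjusted p = 0.00029 with camera and an adjusted p = 0.312 with an estimated correlation. Cytosolic ribosomal protein genes had lower means in 51 of 52 (median -0.17, camera adjusted p = 3.67e-06, and adjusted p = 0.730 with an estimated correlation). Circadian clock genes had lower means in 15 of 17 (median -0.41, camera adjusted p = 0.0191, and adjusted p = 0.560 with an estimated correlation), and interferon response genes in 11 of 12 (median -0.29, camera adjusted p = 0.0314, and adjusted p = 0.538 with an estimated correlation). The sampling hour is not in the labels used here. The remaining called lists were higher, with small medians: collagens and basement membrane 0.08 (camera adjusted p = 0.00195, adjusted p = 0.586 with an estimated correlation), angiogenesis 0.14 (0.0221, adjusted p = 0.538 with an estimated correlation) and fibroblasts 0.05 (0.0334, adjusted p = 0.730 with an estimated correlation). Some of these calls depended on single libraries. The ribosomal list missed the threshold without the 24 h library of replicate 2 (median -0.10, adjusted p = 0.0822), and the circadian list without rest replicate 3 (-0.23, 0.121) or 24 h replicate 3 (-0.36, 0.0833). The interferon list missed it without rest replicate 2 (-0.23, 0.216) or 4 (-0.28, 0.123), or 24 h replicate 1 (-0.29, 0.178) or 3 (-0.26, 0.0833), so its median stayed close to the one reported. The collagen list missed it without rest replicate 1 (0.05, 0.105) or 24 h replicate 2 (0.05, 0.140), and the angiogenesis list without rest replicate 1 (0.15, 0.105) or 24 h replicate 2 (0.04, 0.432), and after median-of-ratios scaling (0.22, 0.0543). The fibroblast list missed it without rest replicate 1 (0.02, 0.558) or 2 (-0.01, 0.226), without 24 h replicate 3 (0.02, 0.247), and after median-of-ratios scaling (0.13, 0.0840). With the calls kept, the collagen median was 0.04 without rest replicate 2, 0.15 without rest replicate 3, 0.05 without rest replicate 4 and 0.13 without 24 h replicate 3. Likewise the angiogenesis median was 0.08 without rest replicate 2, 0.22 without 24 h replicate 1 and 0.07 without 24 h replicate 3. The fibroblast median was 0.32 without rest replicate 3, 0.02 without rest replicate 4, 0.19 without 24 h replicate 1 and 0.17 without 24 h replicate 2. After median-of-ratios scaling the ribosomal median was -0.08 and the collagen median 0.14, with both calls kept.

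Of 43 gene lists fixed in advance, 36 had at least 5 tested members here, and 14 passed, 9 higher and 5 lower. None of the 14 passed with an estimated correlation or with limma's fry, a rotation test of 1-way movement, in which 4 lists had an unadjusted p under 0.05. The split was 7 higher and 6 lower after median-of-ratios scaling, 6 and 5 after quantile normalisation, and 7 and 7 with mitochondrially encoded genes removed. The fibroblast list also missed the threshold with mitochondrially encoded genes removed (median 0.15, adjusted p = 0.0978), after quantile normalisation (0.14, 0.0825) and with a mean of 5 TPM (0.03, 0.243), and the angiogenesis list after quantile normalisation (0.22, 0.0541). With a length and GC trend removed the fibroblast list missed it again (0.12, 0.0783), and with calls kept the medians were 0.16 for respiratory chain, 0.12 for tricarboxylic acid cycle, 0.17 for collagen, 0.22 for angiogenesis and -0.11 for ribosomal lists. With a pseudocount of 5 they were 0.04 for collagen, 0.08 for angiogenesis, 0.03 for fibroblast, -0.14 for interferon and -0.23 for circadian lists, with calls kept. The median log2 change of all tested genes was -0.08.

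Over single genes, 2 of 11863 rose and 0 fell at an adjusted p under 0.05 in limma, with 980 genes at an unadjusted p under 0.05 where 593 were expected. Both fell outside the naming rule and are named because the count is small. BTF3L4P2, annotated as a pseudogene, so that its reads are uncertain, was listed at 0 in all 4 libraries at rest and had 5.53 ± 2.05 TPM (SD, n = 3) at 24 h (adjusted p = 0.00257). ENSG00000286070, which has no symbol, had 0.776 ± 0.413 and 6.97 ± 1.95 TPM (log2 change 2.16, SE 0.23, adjusted p = 0.0262). ENSG00000286070 missed the threshold without rest replicate 1 (adjusted p = 0.133), 2 (just above 0.05) or 4 (0.0670). The count went to 0 when any 1 of the 3 libraries at 24 h was left out, which also took BTF3L4P2 below the low-value filter. It went to 1 without rest replicate 1 and to 4 without rest replicate 2, and to 0 with no low-value filter or with a minimum mean of 5 TPM. Among genes that missed the threshold but had the smallest p in their direction, the sarcomere protein gene MYBPH (chromosome 1, 203167811 to 203175813) had 4.24 ± 3.53 TPM at rest and 45.4 ± 37.0 at 24 h (log2 change 3.08, SE 0.63, adjusted p = 0.376). LDHB, a lactate dehydrogenase subunit (chromosome 12, 21635342 to 21757857), had 89.5 ± 6.73 and 180.0 ± 50.3 TPM (log2 change 0.97, SE 0.17, adjusted p = 0.345), and FAM166B had a log2 change of -1.27 (SE 0.18, adjusted p = 0.171). PDK4, a kinase that restrains pyruvate oxidation, had 183 ± 206 and 21.8 ± 24.1 TPM (adjusted p = 0.639). The monocyte attractant gene CCL2 (log2 change 0.30), the macrophage marker CD68 (-0.02), ANKRD1 (0.32, SE 1.04), PPARGC1A (0.05) and the satellite cell marker PAX7 (-0.15) did not pass, and the sign of CD68 flipped to 0.02 after median-of-ratios scaling.

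The second comparison asked what differed after 6 weeks of resistance training. Genes of sarcomere and cytoskeleton stress were higher: 15 of 16 were higher (median log2 change 0.59), 4 rose over all genes and 8 when adjusted over the list alone. ANKRD2 (chromosome 10, 97572499 to 97583884), a stretch-responsive muscle gene, had 280 ± 137 TPM before and 800.2 ± 293 after (SD, n = 3 each; log2 change 1.59, SE 0.29, limma adjusted p = 0.0183). FLNC (chromosome 7, 128830377 to 128859274) had 65.6 ± 18.3 and 171 ± 68.0 TPM (1.33, SE 0.20, adjusted p = 0.00431), and the actin-binding gene XIRP2 (chromosome 2, 166888487 to 167259753) 215 ± 60.7 and 428 ± 141 (0.97, SE 0.16, adjusted p = 0.00767). MUSTN1 also rose (1.04, adjusted p = 0.0250), while CSRP3 missed the threshold with 3765 ± 1470.4 and 6714 ± 1285 TPM (0.88, adjusted p = 0.0786). Pairs moved unequally: without pair 1, ANKRD2 (0.98, adjusted p = 0.112), XIRP2 (0.99, 0.0965) and MUSTN1 (0.80, 0.527) missed the threshold, without pair 2 MUSTN1 did (1.01, 0.0584), and without pair 3 ANKRD2 did (1.58, 0.215), while FLNC passed each time. Fits without 1 pair kept 1 residual degree of freedom, and without pair 1 or pair 2 the variance came from the trend over genes alone. A pass or a miss there, in this and the later paragraphs, thus says little about the spread of the gene itself. The sarcomere stress list passed camera (adjusted p = 4.91e-08) and did not pass with an estimated correlation (adjusted p = 0.581). With a length and GC trend removed its median was 0.36, with the call kept.

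The largest rise among named genes was in MYBPH, with 57.3 ± 85.7 TPM before and 480.0 ± 466 after (log2 change 4.26, SE 0.37, adjusted p = 1.02e-05), higher in 3 of 3 pairs. ACTC1, the cardiac form of alpha-actin (chromosome 15, 34788095 to 34795726), had 72.4 ± 57.4 and 400 ± 276 TPM (2.45, SE 0.18, adjusted p = 1.78e-06). GJD2-DT, annotated on the opposite strand over an interval that holds ACTC1, rose too (2.36), and reads of the pair cannot be told apart where counting did not use strand. Other rises among named genes were in PANX1 (1.62), AKR1B15 (1.60), NMRK2 (1.58) and LINC00702 (1.83). TSPAN8, a membrane tetraspanin gene (chromosome 12, 71125085 to 71441898), fell from 70.2 ± 10.8 to 21.9 ± 2.46 TPM (-1.63, SE 0.19, adjusted p = 0.000385), and the secreted phospholipase gene PLA2G2A (chromosome 1, 19975431 to 19980416) from 10.7 ± 3.68 to 1.70 ± 0.697 (-2.10, SE 0.30, adjusted p = 0.00249). PDK4 (chromosome 7, 95583499 to 95596491) fell from 511 ± 260 to 282 ± 207 TPM (-0.96, SE 0.18, adjusted p = 0.0183). PPDPFL (-1.36), CCL14 (-1.25), UPK3A (-1.23) and ATF7IP2 (-1.56) also fell. Without pair 1, NMRK2 (0.98, adjusted p = 0.101), PDK4 (-0.79, 0.420) and CCL14 (-1.23, 0.157) missed the threshold. Without pair 2, AKR1B15 (1.20, 0.0784), CCL14 (-1.04, 0.0875), UPK3A (-0.93, 0.112) and ATF7IP2 (-1.03, 0.175) did, and without pair 3, AKR1B15 (1.71, 0.0792), PDK4 (-0.94, 0.0594), UPK3A (-1.26, 0.137) and ATF7IP2 (-1.88, 0.0646) did.

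**Figure D2:**
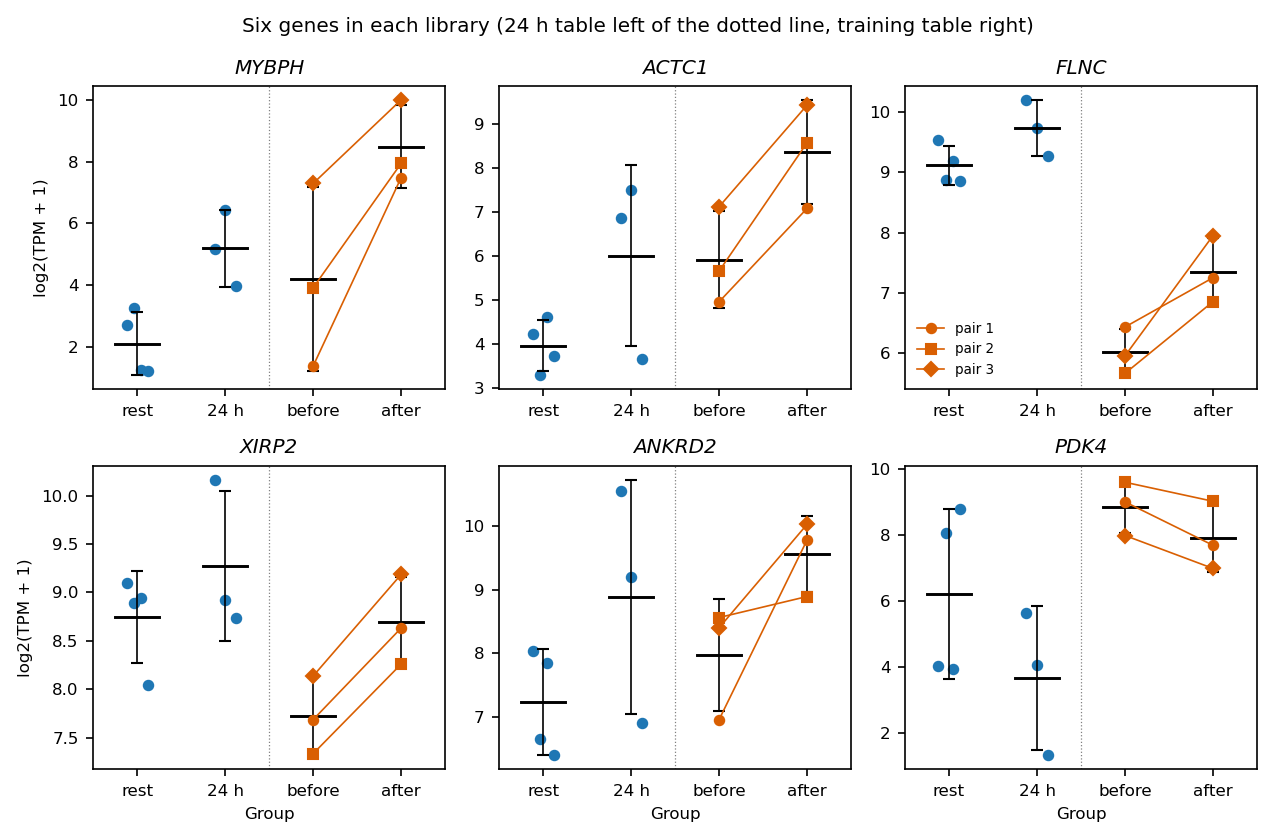
Log2(TPM + 1) of 6 genes (vertical axes) in each library of the 4 groups (horizontal axes); points are libraries, lines join the 3 training pairs, and bars give the group mean ± SD. MYBPH has a log2 change of 4.26 after training, and PDK4 one of -0.96.

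Markers of pericytes and smooth muscle and genes of collagens and basement membranes were higher after training. Of 12 markers of pericytes and smooth muscle, 10 were higher (median 0.74), 2 rose over all genes and 7 adjusted over the list alone. Smooth muscle myosin, MYH11, rose from 7.96 ± 3.92 to 26.2 ± 10.8 TPM (1.59, adjusted p = 0.00603) and smooth muscle actin, ACTA2, from 134 ± 93.9 to 243 ± 147 (0.92, adjusted p = 0.0199; 0.76 without pair 1, adjusted p = 0.454), while TAGLN (1.05, adjusted p = 0.0714) and the pericyte marker RGS5 (-0.23) did not pass. Of 33 collagen and basement membrane genes, 29 were higher (median 0.55), 0 rose over all genes and 10 adjusted over the list alone, with COL3A1 at 38.1 ± 16.5 and 65.8 ± 24.7 TPM (0.79, adjusted p = 0.0701). Endothelial markers (median 0.08), fibroblast markers (-0.06) and matrix proteases (0.37, camera adjusted p = 0.0541) did not pass. The pericyte and collagen lists had adjusted p = 1.5e-05 and 1.37e-06 with camera, and adjusted p = 0.664 and 0.581 with an estimated correlation. With the calls kept, the pericyte median was 0.47 without pair 3 and the collagen median 0.31 with a length and GC trend removed. Heat shock chaperones (median 0.31, camera adjusted p = 0.0290, adjusted p = 0.789 with an estimated correlation) and myogenic progenitor genes (median 0.33, camera adjusted p = 0.0460, adjusted p = 0.581 with an estimated correlation) were also higher. After median-of-ratios scaling neither passed (medians 0.11 and 0.14, adjusted p = 0.305 and 0.0906). Without the block, neither passed (adjusted p = 0.0640 and 0.0736).

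Cytosolic ribosomal protein genes were lower after training in 51 of 52 (median -0.26), with RPL30 at 408 ± 14.2 TPM before and 304 ± 12.5 after; 0 fell over all genes or adjusted over the list alone. Camera gave an adjusted p = 5.98e-20, and an adjusted p = 0.664 with an estimated correlation. The median was -0.16 without pair 3 and -0.47 after median-of-ratios scaling, with the call kept. All 5 tested metallothioneins, which bind zinc and copper, were lower (median -0.48), and MT1X fell from 597 ± 91.8 to 326 ± 42.3 TPM (-0.87, adjusted p = 0.0335; list adjusted p = 3.01e-05 with camera and adjusted p = 0.581 with an estimated correlation). MT1X missed the threshold without pair 1 (-0.86, adjusted p = 0.275) or 3 (-0.69, 0.113), and the median of the list was -0.86 without pair 2. Complement genes were lower in 8 of 8 (median -0.14), T and NK cell markers in 5 of 6 (-0.45), fast fibre genes in 10 of 12 (-0.21), proteasome subunits in 24 of 28 (-0.13), macrophage markers in 11 of 15 (-0.07) and respiratory chain subunits in 34 of 49 (-0.05). Camera gave these adjusted p = 0.000598, 0.00151, 0.00104, 0.000507, 0.00286 and 0.00201, in that order. The complement and macrophage lists share C1QA, C1QB and C1QC, with C1QA at -0.88 and C1QB at -1.03, so they are not separate findings. With an estimated correlation the adjusted p were 0.581 for complement, T and NK cell, fast fibre and macrophage lists, 0.789 for proteasome subunits and 0.818 for respiratory chain subunits. Without pair 1 the macrophage list did not pass (median 0.07, adjusted p = 0.175). Without pair 2 the T and NK cell (-0.27, 0.326), fast fibre (-0.21, 0.0725) and heat shock (0.23, 0.542) lists did not, the fast fibre median being as reported to 2 decimals. Without pair 3 the proteasome (-0.000184, 0.248), heat shock (0.16, 0.103) and respiratory chain (0.10, 0.0712) lists did not. The myogenic progenitor list missed the threshold without pair 1 (0.32, 0.144), 2 (0.44, 0.221) or 3 (0.08, 0.0678), and the respiratory chain list after quantile normalisation (-0.02, 0.490). With the calls kept, medians without pair 1 were 0.50 for heat shock, -0.07 for proteasome and -0.10 for respiratory chain lists. Without pair 2 they were -0.05 for complement, -0.27 for proteasome, -0.19 for respiratory chain and 0.06 for macrophage lists (the last still lower relative to other genes), and without pair 3 -0.38 for complement, -0.13 for fast fibre and -0.32 for macrophage lists. Median-of-ratios scaling also kept these calls, with medians of -0.41 for complement, -0.42 for fast fibre, -0.34 for proteasome, -0.20 for macrophage and -0.26 for respiratory chain lists, and the T and NK cell median was -0.23 with mitochondrially encoded genes removed.

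Of 12824 genes tested, 56 changed, 38 up and 18 down, 49 of them at least 2-fold, and 1455 genes had an unadjusted p under 0.05 where 641 were expected. That count depended on the scaling and on the pairing: it was 0 after median-of-ratios scaling, 1 (higher) after quantile normalisation and 0 in the fit without the volunteer block. All 56 kept their direction in these fits, which is no separate evidence. With complete pairs, leaving out the block keeps each log2 change the same by design, and the scalings shifted genes by little beside the changes of called genes. After median-of-ratios scaling the median absolute log2 change of the 56 was 1.36 with a median SE of 0.24, against 1.36 and 0.25 as reported. Meanwhile limma's prior degrees of freedom went from 15.5 to 6.00. The median log2 change of all genes was 0.14 on TPM as deposited and -0.03 after that scaling, so rises of single genes stand against a general shift of 0.14. The count was 129 without pair 2, 73 without pair 1 and 47 without pair 3, and of the 56 genes, 40, 31 and 31 still passed. In each of these fits 1 residual degree of freedom was left, and the prior degrees of freedom were infinite without pair 2 or pair 1 and 9.14 without pair 3, so the 2 higher counts rest on a variance taken from the trend over genes alone. Of 38 gene lists tested, 13 passed, 5 higher and 8 lower, and none passed with an estimated correlation or with fry, where 6 had an unadjusted p under 0.05. The split was 3 higher and 8 lower after median-of-ratios scaling, 7 and 7 after quantile normalisation, and 3 and 9 with a length and GC trend removed, an alternative chosen after the data were seen. The myogenic progenitor list also missed the threshold with mitochondrially encoded genes removed (median 0.29, adjusted p = 0.0762) and with a mean of 5 TPM (0.24, 0.587). With the length and GC trend removed the heat shock (median 0.15, adjusted p = 0.0543) and myogenic progenitor (0.17, 0.128) lists missed the threshold, and with calls kept the medians were -0.29 for complement, -0.24 for macrophage and -0.08 for respiratory chain lists. With a pseudocount of 5 they were 0.44 for pericyte, 0.29 for collagen, 0.21 for myogenic progenitor, -0.30 for metallothionein and -0.18 for T and NK cell lists, with calls kept. The T and NK cell median was -0.68 with a pseudocount of 0.1 and the macrophage median -0.45 with a mean of 5 TPM, with both calls kept.

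**Figure D3:**
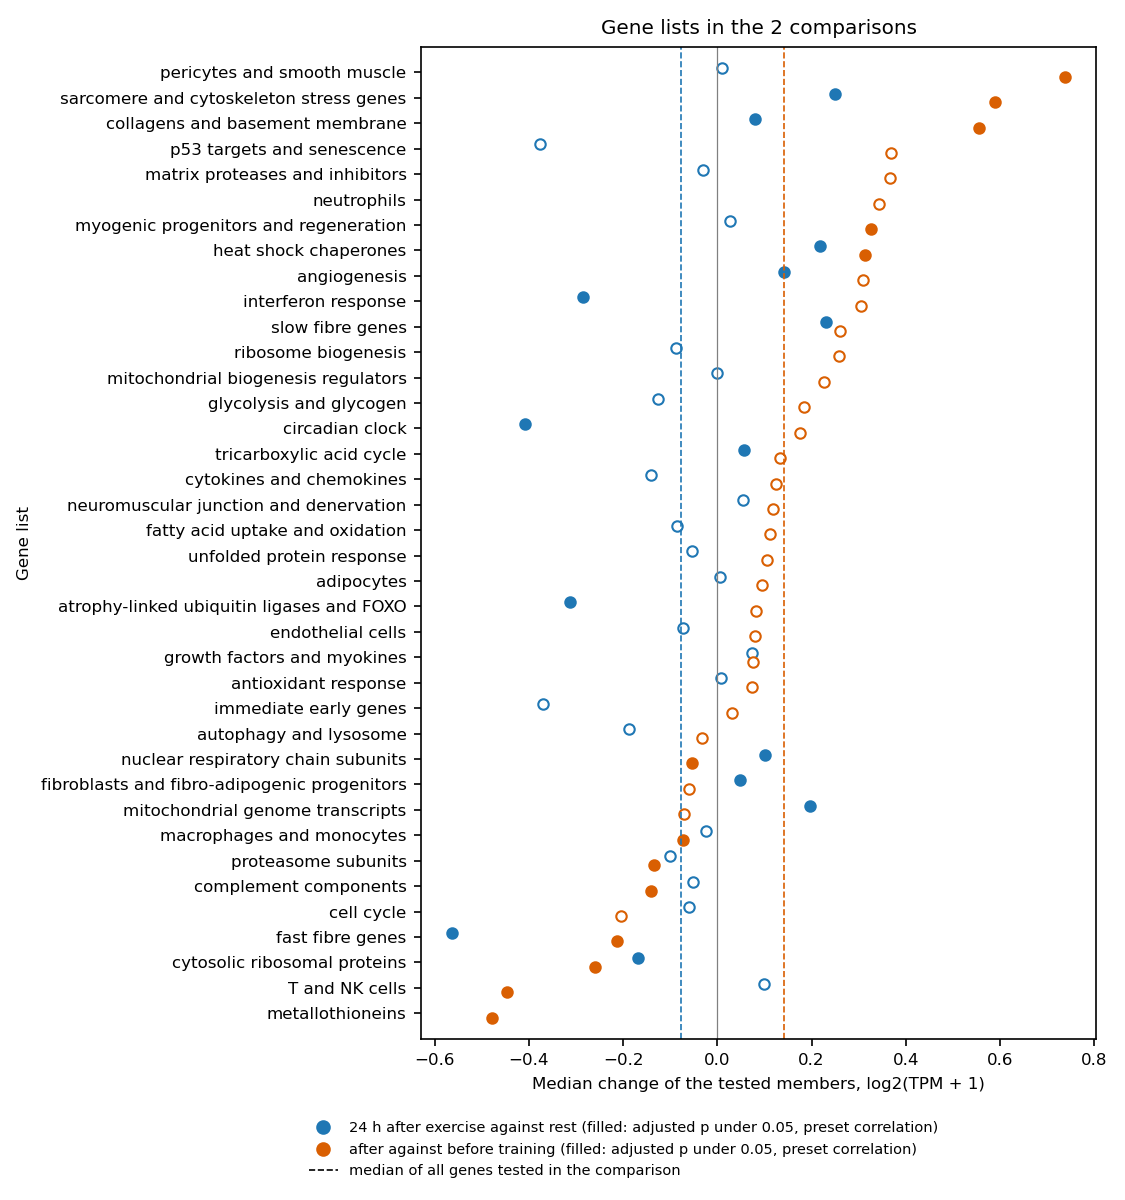
Median log2 change of the tested members (horizontal axis, log2(TPM + 1) scale) of each gene list (vertical axis) at 24 h against rest and after against before training; filled points passed camera with its preset correlation and dashed lines are the medians of all genes. Fast fibre genes lie at -0.56 at 24 h, and pericyte and smooth muscle genes at 0.74 after training.

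The responses were then compared, within the limit that intervention, muscle named and kit differ together, and the muscle sampled and the volunteers may as well. In a fit of all 13 libraries, 1 of 10925 genes differed, BTF3L4P2 (training minus 24 h -3.32, adjusted p = 0.000788), with 1414 genes at an unadjusted p under 0.05 where 546 were expected. Of 35 lists, 11 passed camera for training minus 24 h, 3 higher and 8 lower relative to other genes. The split was 5 and 7 after median-of-ratios scaling. The median difference of all genes was 0.23, so a list with no difference lay below other genes. Circadian clock genes had a median of 0.17 in training and -0.41 at 24 h (camera adjusted p = 0.0262, adjusted p = 0.803 with an estimated correlation), p53 and senescence genes 0.37 and -0.38 (0.0298, adjusted p = 0.726 with an estimated correlation), and collagens 0.55 and 0.08 (0.0328, adjusted p = 0.803 with an estimated correlation). Respiratory chain subunits had -0.05 and 0.10 (camera adjusted p = 2.66e-12, adjusted p = 0.782 with an estimated correlation) and mitochondrial genome transcripts -0.07 and 0.20 (7.16e-07, adjusted p = 0.782 with an estimated correlation). The fast fibre list did not differ by this test (adjusted p = 0.166), nor did sarcomere stress genes (0.636) or heat shock chaperones (0.238).

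No gene was called in both comparisons. Among genes at an unadjusted p under 0.05 in each, 59 were higher in both where 17.5 were expected, and 41 were lower in both where 16.4 were expected. Fisher's exact test across genes, which are not independent, gave 1-sided p = 1.08e-17 and 4.19e-08. After median-of-ratios scaling 58 were higher and 63 lower in both, where 16.4 and 25.9 were expected. Without the volunteer block 30 and 24 were, where 9.48 and 7.63 were expected. Of the genes called in training and tested in both, 26 of 31 that rose and 13 of 13 that fell had the same sign at 24 h. Log2 changes correlated weakly across genes (Pearson 0.18, Spearman 0.13), as a description only. Without training pair 2 Pearson's value was 0.115, the lowest over 10 fits that each left out 1 library or pair, and the highest was 0.217.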

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

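The removal of length and GC trends, the test of a rise of other transcripts and the single-library tests of the slow fibre, respiratory chain and mitochondrial genome lists were chosen after the data were seen. Apart from the counts of splits, the other tests of explanations were written for patterns already seen in the results. Bounds for the fast fibre and ribosomal medians were set from their reported sizes.

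The lower fast fibre genes at 24 h, beside higher slow fibre, respiratory chain and mitochondrial genome lists, were weighed against 3 explanations with camera's preset correlation; as reported, the fast fibre list had an adjusted p = 0.538 with an estimated correlation. Scaling by the mitochondrial share was argued against as the whole cause by the size of the change. With those transcripts removed the fast fibre median was -0.455, while the median of all genes went from -0.08 to 0.01. The camera call stayed (adjusted p = 5.28e-08), but camera compares a list with other genes, so a shared shift hardly moves it and the call is no separate evidence. A single deviating library was argued against as the whole cause by the medians of the fast fibre and mitochondrial genome lists. With 1 library left out, the medians nearest to 0 were -0.393 and 0.155 (highest camera adjusted p 1.63e-05 and 0.00158). The respiratory chain median was 0.0555 without 24 h replicate 1, so that library may carry part of it (highest camera adjusted p 1.40e-05). These kept calls are weak evidence. Estimated correlations were 0.419 for fast fibre, 0.327 for respiratory chain and 0.499 for mitochondrial genome lists, far above the preset 0.01. A single library may account for the slow fibre list, which lost its call without 24 h replicate 1 (camera adjusted p = 0.0686, median 0.0417). The libraries at 24 h were unequal, though. The mean of fast minus that of slow fibre genes on the log2 scale was 0.892 to 1.69 at rest. In 24 h replicates 1, 2 and 3 it was -0.365, 1.33 and 0.601, so replicate 2 lay within the range at rest. A different mix of fibres in the biopsies may account for the pattern, in which 11 slow fibre genes were higher while 12 fast fibre genes were lower. These counts restate the pattern itself, so they cannot tell a mix of fibres from a change within fibres. A change within fibres stays open and untested. Chance cannot be excluded for the number of lists: 7 of the 35 splits of these libraries, the real one included, gave 14 or more, the highest other being 20.

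The lower ribosomal protein genes after training were weighed against 3 technical explanations with camera's preset correlation; as reported, the list had an adjusted p = 0.664 with an estimated correlation. A trend on transcript length and GC content was argued against as the whole cause, since the median was -0.302 with it removed (camera adjusted p = 7.88e-16). Its removal also took the median of all genes from 0.14 to 0.00284. Relative to all genes the list thus lay less low than as reported, so the trend may account for a part. A single pair was argued against as the whole cause only by the size of the change: without 1 pair, the median nearest to 0 was -0.162. Over the 3 pairs the list median ranged from -0.480 in pair 3 to -0.0972, so pair 3 may carry a part. The camera call stayed without any 1 pair (highest adjusted p 2.76e-08), but that is weak evidence. The estimated correlation of the list was 0.794, far above the preset one, so a small shared drift could keep the call. A rise of other transcripts, which would lower every share alike, was argued against as the whole cause, since the median of all genes was 0.14. After median-of-ratios scaling the list median was -0.466 (camera adjusted p = 1.42e-15), which is no separate evidence. With all genes at 0.14 that scaling lowers every list, and a shared shift hardly moves camera. An effect of training stays open and was not tested apart from these.

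The higher pericyte, smooth muscle and collagen genes after training (adjusted p = 0.664 and 0.581 with an estimated correlation) could come from more vessel and connective tissue in the later biopsies. Against this for the pericyte list, its median exceeded the endothelial and fibroblast medians in all 3 pairs, by at least 0.388, and the smaller gap of the medians over genes was 0.658. The collagen list was not put to this test, so for it the explanation stays open. In pairs 1, 2 and 3 its medians were 0.429, 0.561 and 0.627. Endothelial medians were -0.0323, -0.145 and 0.362, and fibroblast medians -0.103, 0.00312 and 0.247. Whether contractile genes rose without the other pericyte markers cannot be told apart, since the smallest gap over pairs was 0.122 (0.389 over genes, 1.05 against 0.66). A larger share of smooth muscle alone, such as part of an arteriole, stays open.

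In all counts of splits the real one is included. Of the 35 splits of the 24 h libraries, 3 gave as many genes (2 as reported, highest other 2), so chance cannot be excluded. In training, 10 splits are too few for a share under 0.05: the real split gave 56 genes and the highest other 14, or 5 among the 4 splits that part all 3 pairs. For lists in training, 3 of 10 gave as many, with 13 in the real split and 13 in the highest other. For the difference, 14 of 100 drawn splits gave at least 1 gene (highest other 14) and 18 of 100 at least 11 lists (highest other 16), so chance cannot be excluded.

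In the rest group, 7 of 85 values had 1 library far from the other 3, by a gap over range that chance exceeds in about 1 of 20. The ratios were 0.838 for EXTL1, 0.929 for TNNC2, 0.885 for ENPP5, 0.931 for MUSTN1, 0.848 for MYH7 and 0.837 for CCL2. For the globin share the ratio was 0.949, with 1.46% in rest replicate 2 and 0.0517% to 0.124% in the others.

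Responses that differed between the comparisons, as training minus 24 h, were BTF3L4P2 at -3.32 and the medians of 11 lists. These were macrophages -0.0266, fibroblasts -0.21, collagens 0.46, slow fibre genes -0.12, respiratory chain -0.16, mitochondrial genome -0.27, ribosomal proteins -0.0943, proteasome -0.0180, complement -0.15, p53 and senescence 0.87, and circadian clock 0.77. With an estimated correlation the adjusted p were 0.726 to 0.803. The median difference of all genes was 0.23.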

How the results depend on the processing

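Removal of length and GC trends was chosen after the data were seen. In the 24 h comparison, 1547 values of single genes kept their direction and side of the threshold. Another 12 lost the call, 1 gained it and 23 changed sign. Only 2 genes were called there, so nearly all values that kept both belong to uncalled genes, which had no call to lose. In training, with 56 genes called, 1070 kept both, 411 lost the call, 41 gained it and 6 changed sign. The causes of the changes below were not tested unless stated, and what depth limits is unknown. The 2 genes called at 24 h became 1 with a pseudocount of 0.1, 0 with no filter, 0 with a mean of 5 TPM (where neither was tested), 1 with the length and GC trend removed, and 0 to 4 when 1 library was left out. The replicate numbers at 24 h did not pair the libraries (correlations -0.01 to 0.04, others -0.11 to 0.07, own number best in 1 of 3). The fit with the replicate block also left out rest replicate 4, whose number has no library at 24 h: it gave 1 gene, MYBPH, and 15 lists, against 2 genes and 13 lists without that library and without the block. The 14 lists became 0 with an estimated correlation and 0 with fry, and ranged from 12 to 14 when 1 library was left out.

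The 56 genes called in training became 26 with a pseudocount of 0.1, 0 with no filter, 0 after median-of-ratios scaling, 1 after quantile normalisation, 9 without an intensity trend, 2 with the length and GC trend removed, 93 with a mean of 5 TPM and 585 with array weights. Without the replicate block the count was 0 and the lists 11, of which heat shock and myogenic progenitors were the only list calls lost. The count was 47 to 129 when 1 pair was left out. The 13 lists became 0 with an estimated correlation and 0 with fry, and ranged from 11 to 13 when 1 pair was left out. The 1 gene that differed between responses became 2 with a pseudocount of 5 and 4 with array weights. The correlation of log2 changes was 0.225 with a pseudocount of 5 and 0.257 with a mean of 5 TPM, and 0.115 to 0.217 when 1 library or pair was left out.

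The genes whose values changed sign did not pass as reported. Ranges are over the fits that left out 1 library or pair and still tested the gene, which for MYH3 at 24 h were 4 of 7. At 24 h, CD68 was 0.00247 with a pseudocount of 0.1, 0.0228 after median-of-ratios scaling, 0.0505 without mitochondrial genes, 0.0251 after quantile normalisation, 0.0253 with array weights, 0.0390 with the length and GC trend removed, and -0.149 to 0.128 over left-out libraries. MYH3 was 0.0287, 0.0395 and 0.0417 with those 3 scalings, 0.0619 with the trend removed, and -0.144 to 0.134 over left-out libraries. PPARGC1A was -0.0156 with array weights and -0.118 to 0.206 over left-out libraries. ANKRD1 was -0.522 without rest replicate 4, with or without the replicate block, and -0.522 to 1.18 over left-out libraries, COL4A1 -0.0940 to 0.196 and HSPA1A -0.0123 to 0.338. In training, HSPA1A was -0.00960 with array weights and -0.0228 with the trend removed, and over left-out pairs CD68 was -0.321 to 0.158, MYC -0.207 to 0.0833 and ANKRD1 -0.0808 to 0.920. The respiratory chain list, which had passed, ranged from -0.193 to 0.0997, the latter without pair 3.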

Other observations

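At an unadjusted p under 0.01 in both settings, a selection made after the data were seen, 20 genes were found, of which 14 had the same direction in both and 6 had opposite directions. Those higher in both included MYBPH (log2 change 3.08 at 24 h and 4.26 in training), the co-chaperone gene DNAJA4 (1.22 and 1.03), the hindlimb transcription factor gene PITX1 (1.92 and 1.06), ITIH4 (0.83 and 1.43) and EXTL1 (1.26 and 0.88). Those lower in both included the transcription factor gene CEBPD (-2.15 and -0.70), PPDPFL (-1.89 and -1.36), MLF1 (-1.01 and -0.69) and LANCL1-AS1 (-0.77 and -1.33). Opposite in direction were MYOM2, a sarcomere M-band gene (-0.41 and 0.85), MT-TM (2.97 and -0.96), RN7SKP70 (-1.38 and 1.24), PRRT4 (-0.73 and 0.92), SEL1L2 (1.21 and -0.85) and SNCG (-0.61 and 0.79). None passed the adjusted threshold at 24 h.

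Among the 18 genes that fell after training, 3 were transfer RNA genes of the mitochondrial genome: MT-TD (-2.77), MT-TL2 (-1.77) and MT-TT (-1.09). MT-TT missed the threshold without pair 1 (adjusted p = 0.0642), 2 (0.112) or 3 (0.0927), while MT-TD kept its call without pair 1 or 2 and MT-TL2 without pair 1 or 3, each falling below the low-value filter in the remaining fit. Transfer RNAs are short RNAs that poly(A) selection does not target, and the mitochondrial genome list of protein-coding transcripts did not pass (median -0.07). Other genes that rose included HSPB6 (1.22), with 623 ± 321 TPM before and 1435 ± 641 after (SD, n = 3 each), the extracellular matrix gene THBS4 (1.27), CAMK2D (1.08), the cell cycle inhibitor CDKN1A (1.48) and the lymphatic chemokine CCL21 (1.13). Without pair 1, HSPB6 (1.09, adjusted p = 0.0512), THBS4 (1.20, 0.0600), CAMK2D (1.13, 0.0505) and CCL21 (1.16, 0.0974) missed the threshold, as did CCL21 without pair 2 (0.94, 0.191) and CDKN1A without pair 3 (1.25, 0.206).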
